A study of Arabidopsis thaliana with 4 samples.

How the data were processed

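Chromatin immunoprecipitation libraries were made from mature rosette leaf and leaf-derived callus with antibodies against acetylated H3 and against H3K4me3, per the labels' protocols, 1 library per tissue and mark. The submitters' processing notes name Bowtie2 2.3.4.3, SAMtools 1.11, HOMER 4.10.4 and the TAIR10 build, without saying which step each served. How reads were filtered and which settings the region calls used are not given in the sources used here. No input or control library enters the tables, so DNA that was recovered without the mark is not subtracted.

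Regions were called separately in the callus and the leaf library and merged with HOMER mergePeaks, per the file headers. Each merged region carries a score, which the authors deposited with it and which was used here only to describe and to match regions within a list. The authors then compared callus with leaf at the merged regions with HOMER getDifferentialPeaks, per the file headers, keeping regions with at least 2-fold more tags in callus and a Poisson p-value of at most 0.01. The tag signal in the deposited tables is the number of tags in the 147 bp around the region centre, so a long region is judged by its centre alone. Leaf tags were deposited unscaled in steps of 0.5 and callus tags after scaling to the leaf library. The fold in the deposited tables is the ratio of these numbers. Only regions higher in callus are listed, so no tag numbers of regions lower in callus or unchanged were used here.

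The deposited p-value takes the leaf tag number as an exact mean: a Poisson tail with that mean gave the deposited value within 0.1 log10 units for all 1617 H3ac regions and for the 1356 H3K4me3 regions whose p was large enough to compare. It leaves out the counting error of the leaf library and is not adjusted over regions, and no such p is printed here. In its place, the bracketed intervals of folds are exact conditional (Clopper-Pearson form) 95% intervals from both tag numbers, with callus tags put back to their unscaled number. A tag was taken as 1 read. Leaf tags lie on steps of 0.5, and if 0.5 tags were 1 read every interval would be narrower and the exact test would keep more regions. PCR copies are not independent molecules, so intervals cover counting error only.

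The relative depth of the libraries was read from the spacing of the values. Callus tags lay on steps of 0.3652 (H3ac) and 0.4922 (H3K4me3) where leaf tags lay on 0.5, which gives callus to leaf depth ratios of 1.369 and 1.016, and the spacing of the region scores gave the same ratios. These ratios were not checked at unchanged regions. Organelle DNA was recovered too, and if its share differed between libraries, all folds of a mark could shift together. The leaf tag number was 3 or lower in 54 H3ac and 42 H3K4me3 regions, where folds are loosely bounded.

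The design fixed before the data were examined assigned regions through a window around each transcription start. The gene table used here (assembly TAIR10.1) has no strand, so this could not be done. Instead a region was given to every nuclear protein-coding gene that its counted 147 bp overlapped by at least 1 bp, or else to the nearest gene end within 500 bp. The table holds 27444 such genes. Builds were checked by shifting the centres of H3K4me3 regions called in both tissues by up to 4000 bp: in 58 of 58 bins of 2 Mb the unshifted position had the highest share inside genes. Only region coordinates of the authors' files (TAIR10) are printed. Regions on the plastid and mitochondrial genomes were not given to genes. A gene counts as listed as higher when any of its regions is, with the largest fold, and as called in leaf alone when all of its regions were.

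Gene lists and a rule for naming genes were fixed before the data were examined. The rule took, per mark, the 10 genes with a symbol and the largest fold among regions at or above the median callus tags, up to 15 listed peptide hormone genes, up to 4 of each other list, the 10 genes with the largest smaller fold in both marks, and 8 fixed regulators. List members beyond these, all genes named for regions called in leaf alone and the members of families were chosen after their values were seen. The lists cover peptide hormones, peptide receptors, callus and root stem cell factors, embryo and shoot stem cell factors, photosynthesis, leaf development, epidermis with stomata and trichomes, vascular genes, auxin, cytokinin, cell cycle, jasmonate and wounding, histone modifiers and ribosomal proteins. Family patterns on symbols also caught 14 genes that only share a symbol, none of them listed as higher. The peptide hormone list was drawn mostly by symbol and takes in the RTFL and PROPEP families. Whether its members are secreted was not checked. Each list count stands beside 10000 random lists drawn from genes with a region of that mark and matched on region score in 10 strata. These percentiles describe the 4 libraries and are not p-values.

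Alternatives fixed before the data were examined were a 4-fold limit, a p limit of 1e-06, a median limit on callus tags, assignment by region and gene body, by the nearest gene end within 1000 bp or by at least 50% of the region or gene, random lists matched on gene length, and overlap of regions in place of genes. Rescaling by the median ratio over all regions was not run. Assignment and intervals were tested on simulated data: 300 of 300 sampled assignments per mark matched a plain search, and simulated 3-fold differences lay in 96.1% (H3ac) and 95.8% (H3K4me3) of intervals. The simulated regions were not selected for a high fold as the listed regions were. This coverage therefore does not carry over to intervals of listed regions. With 200 regions changed 4-fold among 20264 at H3ac tag numbers, the exact test with Bonferroni adjustment recovered 117 with 0 false calls, and 162 with 0 false calls among 18564 at H3K4me3 tag numbers. These were the leaf tag numbers of listed regions, repeated over all regions. Tag numbers of unlisted regions are not represented. The simulated libraries had Poisson counting error alone, at depth ratios of 1.3 (H3ac) and 1.05 (H3K4me3). The 0 false calls therefore do not cover variation between libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used.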

Results

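Histone H3 acetylation (H3ac) and trimethylation of H3 lysine 4 (H3K4me3), both marks found at genes in use, were profiled by chromatin immunoprecipitation sequencing in Arabidopsis thaliana Col-0. The tissues were mature rosette leaf and callus grown from leaf explants. Explants came from seedlings aged 2 weeks and spent 15 days on a medium that induces callus, an unorganised dividing tissue. Callus and leaf thus differ in tissue and in time on this medium together, and these cannot be told apart. The series has 4 libraries, 1 per mark and tissue, so no difference below has a replicate check and each one compares 2 libraries rather than tissues. Its title ties histone marks to peptide hormone production as leaf cells become callus, and the comparison asks which genes, peptide hormone genes among them, carry more of a mark in callus than in leaf. The merged lists held 20264 H3ac and 18564 H3K4me3 regions. Tags were listed by the authors for regions higher in callus only, so leaf is described below by regions called in leaf alone, which carry no fold and are no test of a difference. The step of the tag values put the callus H3ac library at 1.369 times the depth of the leaf H3ac library and the callus H3K4me3 library at 1.016 times that of its leaf counterpart. Total depth is unknown. Intervals in brackets are exact 95% intervals from the tag numbers and cover counting error only. They do not allow for the listing of regions by a high fold, so folds and bounds may lie too high.

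For H3ac, genes of the auxin, callus and root stem cell, and peptide hormone lists were among those with more mark in callus. The naming rule took the 10 genes with a symbol that had the largest folds and at least median callus tags. Among them in the authors' deposited table were FTM1 with 24.83-fold (5.54 to 354), a stearoyl desaturase gene, and AHL19 with 18.16-fold (6.45 to 76.7), a DNA-binding AT-hook protein. GH3.3, whose enzyme joins auxin to amino acids, had 15.58-fold (5.09 to 77.5) in the authors' deposited table. The same rule took in AGF1 (15.41-fold), the transporter gene ABCG35 (14.7-fold), OFP7 (12.82-fold), LBD40 (10.59-fold), SRO4 (10.23-fold), IQD15 (9.79-fold) and the transcription factor gene WRKY75 (9.53-fold) from the authors' deposited table. All 10 regions were called in callus alone and lay in the gene body, as did that of FTM1 at chromosome 1, 16577749 to 16579379 (TAIR10). In all, the authors' deposited table listed 1617 H3ac regions as higher in callus, 7.98% of those merged, with a median of 2.92-fold. Of these 1540 lay on nuclear chromosomes and 77 on the mitochondrial genome.

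Of the 128 genes on the peptide hormone list, 45 had an H3ac region and 12 of these (26.7%) were listed as higher in callus. Random lists of the same size, matched on region score, held 1 to 8 in the central 95% of 10000 draws, and 5 of the 10000 held as many. At 4-fold or more, 4 peptide hormone genes were left and 258 of 10000 random lists held as many. RGF3, a gene for a root meristem growth factor peptide, led with 27.39-fold in the authors' deposited table, from 27.4 scaled callus tags and 1 leaf tag (4.63 to 1110). Its region spanned 1276922 to 1277072 on chromosome 2 and lay in the gene body. Next in the authors' deposited table were the CLAVATA3-related peptide genes CLE12 with 6.82-fold (3.21 to 16.9) and CLE11 with 5.18-fold (2.11 to 15.8). RTFL10 (4.53-fold), RGF8 (3.94-fold) and the phytosulfokine precursor gene PSK5 (3.42-fold) followed in the authors' deposited table. The RGF8 region rested on 19.7 scaled callus and 5 leaf tags (1.5 to 13.1). Its counted 147 bp lay outside the gene body but within 500 bp, as did those of PROPEP3 below. The other 6 genes, RTFL2, PROPEP4, PROPEP3, CLE13, RTFL21 and CLE44, had between 2.01 and 2.87-fold in the authors' deposited table. Their lower bounds ran from 1.21 (PROPEP3 and RTFL21) to 1.89 (RTFL2). The count of 12 was not redone with the exact test on both tag numbers. STOMAGEN, a peptide gene of stomatal development, and CLE21, RTFL1 and IDL2 had H3ac regions called in leaf alone, and 5681 of 10000 random lists held at least 4 such genes.

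Transcription factor genes of callus formation and root stem cells stood furthest above their random lists for H3ac. Of 15 list members with a region, 7 (46.7%) were listed as higher, against 0 to 3 in the central 95% of random lists, and 1 of 10000 held as many. They were all AINTEGUMENTA-LIKE or WOX genes, with folds in the authors' deposited table of 12.12 (3.54 to 75.6) for PLT3, 7.4 (2.68 to 28.5) for PLT1, 6.84 (2.85 to 20.6) for BBM and 6.65 (2.52 to 23.3) for PLT2. PLT5 (3.87-fold), WOX11 (3.5-fold, 1.53 to 9.36) and PLT7 (2.88-fold) completed the group in the authors' deposited table. In the auxin list 13 of 67 genes (19.4%) were listed as higher, and 55 of 10000 random lists held as many. Beside GH3.3 these included GH3.1 with 15.83-fold (3.42 to 228), IAA30 with 7.49-fold (3.25 to 21.2) and BRU6 with 6.43-fold (3.02 to 16) in the authors' deposited table. At 4-fold or more, 4 auxin genes were left and 834 of 10000 random lists held as many.

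The remaining lists lay within the central 95% of their random lists for H3ac. Cell cycle genes had 3 of 25 listed as higher, namely CYCA2;4 (3.37-fold), CYCD3;1 (2.1-fold) and CYC3B (2.02-fold) in the authors' deposited table. Cytokinin genes had 2 of 26, the response regulator RR5 (3.12-fold) and the receptor gene WOL (2.09-fold) in the authors' deposited table. The vascular list had 1 of 2, the auxin response factor gene MP with 3.55-fold (1.98 to 6.83) in the authors' deposited table. Just 1 gene each was listed among 21 jasmonate and wound genes (JAZ3, 2.79-fold), 53 histone modifier genes (SDG4, 2.14-fold) and 39 photosynthesis genes (LHB1B2, 2.15-fold) in the authors' deposited table. None was listed among 11 peptide receptor, 9 leaf development, 55 ribosomal protein, 3 epidermis, stomata and trichome genes or the 1 embryo and shoot stem cell gene with an H3ac region. Photosynthesis genes instead had 6 of 39 with regions called in leaf alone (PSAO, Lhca6, CAB1, LHCA2, PSBQA and RBCS1B), a number that 51 of 10000 random lists reached. Such genes also numbered 3 of 26 for cytokinin (ARR7, LOG1 and CKX4; 514 of 10000 random lists held as many), 2 of 25 for the cell cycle (MCM3 and ICK6; 5790), 5 of 67 for auxin (7047) and 3 of 53 for histone modifiers (5391). Light-harvesting and Rubisco small subunit genes have near-identical copies that can share reads, so single members of these families are uncertain.

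The H3ac regions gave 1087 genes listed as higher, 6.51% of the 16689 genes with an H3ac region, and 735 genes whose regions were all called in leaf alone. H3ac tags were few, with a median of 35.8 scaled callus and 12 leaf tags per listed region in the authors' deposited table. The counting interval lay above 1 for 1609 regions and above 2 for 430. The regions were listed for at least 2-fold more of the same tags, so intervals above 1 are no independent check. An exact test on both tag numbers with Bonferroni adjustment over all merged regions, chosen after the data were seen, left 433 of the 1617 (396 of them nuclear), or 1112 if 0.5 tags are 1 read.

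For H3K4me3, root stem cell, auxin and cell cycle genes stood out. Among the 10 genes with a symbol taken by the rule, the authors' deposited table gave 149.33-fold (34.5 to 2090) for NPY4, a gene of auxin-dependent organ formation, and 119.63-fold (21.1 to 4760) for IQD15, a calmodulin-binding protein gene. RGF3 with 115.2-fold (20.3 to 4590) and the sucrose synthase gene SUS4 with 112.24-fold (19.7 to 4470) in the authors' deposited table came next among these 10. These 4 rest on 1 or 1.5 leaf tags, so their upper bounds are loose. IAA30 had 48.37-fold (18.6 to 179), AGL21 44.73-fold (16.1 to 187) and MYB112 42.62-fold (15.4 to 179) in the authors' deposited table. BRU6, a GH3 gene, had 39.31-fold (18.3 to 103), the purine transporter gene AZG2 38.15-fold (14.6 to 142) and BBM, an embryogenesis regulator, 31.11-fold (13.1 to 97.2) in the authors' deposited table. All 10 regions were called in callus alone and lay in the gene body. In all, the authors' deposited table listed 1359 H3K4me3 regions as higher in callus, 7.32% of those merged, with a median of 3.32-fold.

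Of 49 peptide hormone genes with an H3K4me3 region, 13 (26.5%) were listed as higher in callus. Random lists matched on region score held 3 to 13 in the central 95%, and 422 of 10000 held as many, so by this measure the list lay at the edge of its random lists. No random list matched on gene length instead held as many. At 4-fold or more, 8 were left and 78 of 10000 random lists matched on region score held as many. Root meristem growth factor genes led again: in the authors' deposited table RGF1 had 46.93-fold (10.6 to 663), RGF4 33.23-fold (8.86 to 280) and RGF8 23.48-fold (10.8 to 61.9), beside RGF3 above. The H3K4me3 region of RGF3 spanned 1276809 to 1277504 on chromosome 2 and that of RGF1 spanned 24466599 to 24466843 on chromosome 5. RTFL19 (16.34-fold), RTFL10 (10.97-fold), PROPEP4 (7.28-fold) and CLE11 (4.36-fold) followed in the authors' deposited table. RTFL15 (3.94-fold), CLE12 (3.65-fold), PSK5 (2.64-fold), CLE14 (2.3-fold) and IDL4 (2.13-fold) completed the group in the authors' deposited table. STOMAGEN, CLE21, CLE9, RTFL6, IDL3 and RGF9 had H3K4me3 regions called in leaf alone, 6 of 49, and 4219 of 10000 random lists held as many.

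The callus and root stem cell list had 12 of 17 genes (70.6%) listed as higher for H3K4me3, and no random list among 10000 held as many. After BBM, WOX11 had 30.52-fold (10.1 to 151), PLT1 25.16-fold (10 to 85.3) and PLT2 23.72-fold (10.3 to 69.6) in the authors' deposited table. The WOX11 region ran from 890846 to 892201 on chromosome 3, in the gene body. The lateral root gene LBD18 had 9.66-fold, WIND3 3.29-fold, PLT5 3.17-fold and LBD16 2.89-fold (2.06 to 4.12) in the authors' deposited table. PLT7 (2.73-fold), PLT3 (2.61-fold), SHR (2.39-fold) and ARF19 (2.24-fold) were the others in the authors' deposited table. Of the genes fixed for description whatever their value, WOX5, LBD29 and ERF115 had no region of either mark called in either tissue. WIND1 had 1 region of each mark called in both tissues and not listed as higher, and LBD16 had no H3ac region.

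Auxin genes had 21 of 85 (24.7%) listed as higher for H3K4me3, and 18 of 10000 random lists held as many. AT2G24400, a SAUR family gene, had 54.64-fold (9.4 to 2190) on 1 leaf tag, and GH3.3 had 18.67-fold (10.7 to 35.6) in the authors' deposited table. The list had members on both sides: 15 auxin genes, most of them small auxin-up RNA genes such as SAUR24, SAUR26 and SAUR63, had regions called in leaf alone, and 23 of 10000 random lists held as many. Several of these lie side by side as near copies and can share reads. Cell cycle genes had 14 of 46 (30.4%) listed as higher, and 4 of 10000 random lists held as many. CYCA2;4 had 4.4-fold (3.2 to 6.15), CYCB2;1 4.32-fold (2.65 to 7.36), the B-type cyclin gene CYC1BAT 4.22-fold (2.55 to 7.3) and the kinase gene CDKB1;1 4-fold (2.74 to 5.98) in the authors' deposited table. At 4-fold or more, 7 auxin and 4 cell cycle genes were left, numbers that 1335 and 1589 of 10000 random lists reached.

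Cytokinin genes had 6 of 31 (19.4%) listed as higher, and 209 of 10000 random lists held as many. The cytokinin oxidase genes CKX3 with 15.42-fold (7.42 to 37.8) and CKX5 with 3.97-fold (2.86 to 5.62), WOL with 4.75-fold (3.32 to 6.96) and RR1 with 3.1-fold (1.93 to 5.13) led in the authors' deposited table. At 4-fold or more 2 cytokinin genes were left, which 2432 of 10000 random lists reached. A further 4 cytokinin genes, LOG1, IPT3, CKX4 and LOG7, had regions called in leaf alone, and 223 of 10000 random lists held as many. Vascular genes had 2 of 3, MP with 13.26-fold (7.85 to 24.1) and ATHB8 with 3.05-fold (2.21 to 4.29) in the authors' deposited table, and 501 of 10000 random lists held as many. The embryo and shoot stem cell list had 1 of 2 (CUC2, 2.65-fold) and the peptide receptor list 1 of 12 (BAM3, 2.66-fold) in the authors' deposited table. Histone modifier genes had 2 of 57 (SDG35, 5.48-fold, and SDG4, 3.58-fold), jasmonate and wound genes 1 of 23 (LOX1, 2.02-fold) and ribosomal protein genes 1 of 53 (PFL, 4.06-fold) in the authors' deposited table. All 3 counts lay within the central 95% of random lists. For both marks the counted 147 bp of the SDG4 region lay outside the gene body, within 500 bp of it.

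Photosynthesis genes had 0 of 46 listed as higher for H3K4me3 and 10 of 46 (21.7%) with regions called in leaf alone, which no random list among 10000 reached. These were CAB2, CAB3, LHCB2.2, LHCB2.3, LHB1B1, RBCS1A, RBCS1B, RBCS2B, RBCS3B and NPQ4. The first 9 belong to families of near copies, so which member carried the call is uncertain. Of 10 leaf development genes none was listed as higher and 1, the abaxial identity gene FIL, had regions called in leaf alone. The 3 epidermis, stomata and trichome genes with a region were neither listed as higher nor called in leaf alone.

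The H3K4me3 regions gave 1267 genes listed as higher, 7.19% of the 17610 genes with a region, and 689 genes whose regions were all called in leaf alone. Tags were more numerous than for H3ac, with a median of 108.3 scaled callus and 29.5 leaf tags per listed region in the authors' deposited table. The counting interval lay above 1 for all 1359 regions and above 2 for 809, which again is no independent check on regions listed from the same tags.

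**Figure D1:**
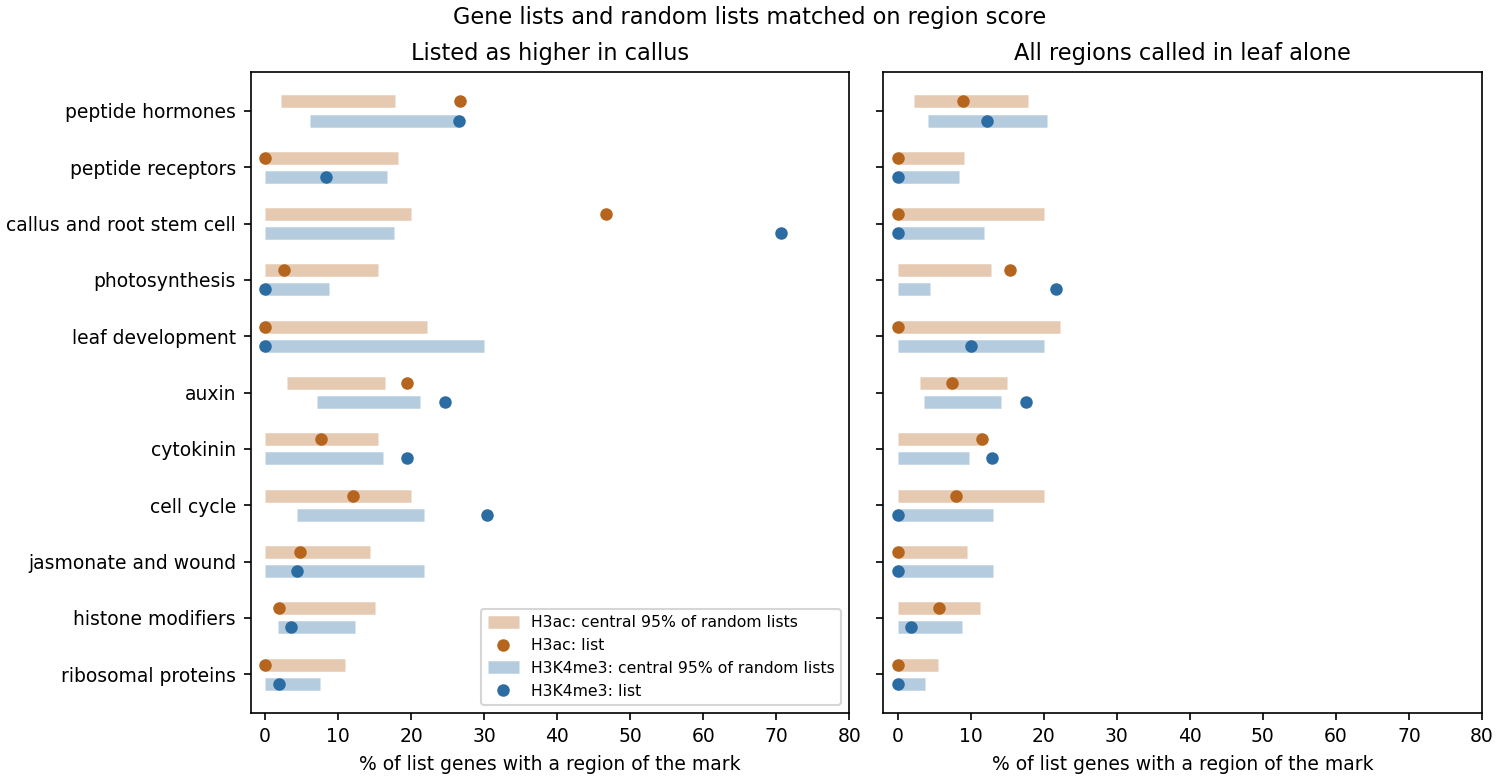
Percent of list genes listed as higher in callus (left) or with all regions called in leaf alone (right), among genes with a region of the mark, for the lists with at least 9 such genes for each mark. Points are the lists and bars the central 95% of 10000 random lists matched on region score; the callus and root stem cell list lies at 46.7% (H3ac) and 70.6% (H3K4me3), beyond its bars, and photosynthesis at 21.7% (H3K4me3) on the right.

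Both marks were higher in callus at many of the same genes, led by AT2G04480, UMAMIT29, RGF3, AT5G53990 and GH3.3 by the smaller of their folds. AT2G04480 had 62.09-fold for H3ac, on 0.5 leaf tags and with a lower bound of 6.31, and 116.84-fold for H3K4me3 (26.9 to 1640) in the authors' deposited table. UMAMIT29, an amino acid transporter gene, had 47.48-fold for H3ac, on 0.5 leaf tags and with a lower bound of 4.75, and 67.28-fold for H3K4me3 (15.4 to 946) in the authors' deposited table. AZG2 had 14.97-fold (3.88 to 128) and 38.15-fold, and OSM34, an osmotin-like defence gene, 23.37-fold (5.2 to 333) and 13.69-fold (5.59 to 43.4) for H3ac and H3K4me3 in the authors' deposited table. FTM1, AT3G22800 and AT3G15240 completed the 10 genes with the largest smaller fold. Of 15711 genes with regions of both marks, 952 were listed as higher for H3ac and 889 for H3K4me3, and 489 for both. Independent lists would share 53.9, and lists drawn within cells of both region scores shared 114 on average and at most 145 in 10000 draws. At 4-fold or more in both, 133 genes were shared, against 5.57 for independent lists and 13 on average (at most 27) for lists matched on both scores. All regions of 212 genes were called in leaf alone for both marks, against 14.2 for independent lists and 49.9 on average (at most 73) for lists matched on both scores. The matched draws for the 133 and 212 genes were chosen after the data were seen.

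Across the 489 shared genes the log2 folds of the marks had a Pearson r of 0.441 and a Spearman rho of 0.388. This relation is across genes, which are not independent replicates, and no p is given. The H3K4me3 fold was the larger at 310 of the 489 (63.4%). With genes assigned here, the largest fold per gene in the authors' deposited table had medians of 4.21-fold for H3K4me3 and 3.53-fold for H3ac. Tags per region differ between the marks, and the size of folds was not compared by a test. Among peptide hormone genes 7 were listed for both marks (RGF3, RGF8, CLE11, CLE12, RTFL10, PROPEP4 and PSK5), 5 for H3ac alone and 6 for H3K4me3 alone. RGF8 was listed for H3ac through a region outside its gene body. All 7 callus and root stem cell genes listed for H3ac were also listed for H3K4me3, with 5 more for H3K4me3 alone. Cell cycle genes had 1 shared gene, 2 for H3ac alone and 13 for H3K4me3 alone, a difference between marks that was not tested. MCM3, among the 13, had its H3ac called in leaf alone.

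**Figure D2:**
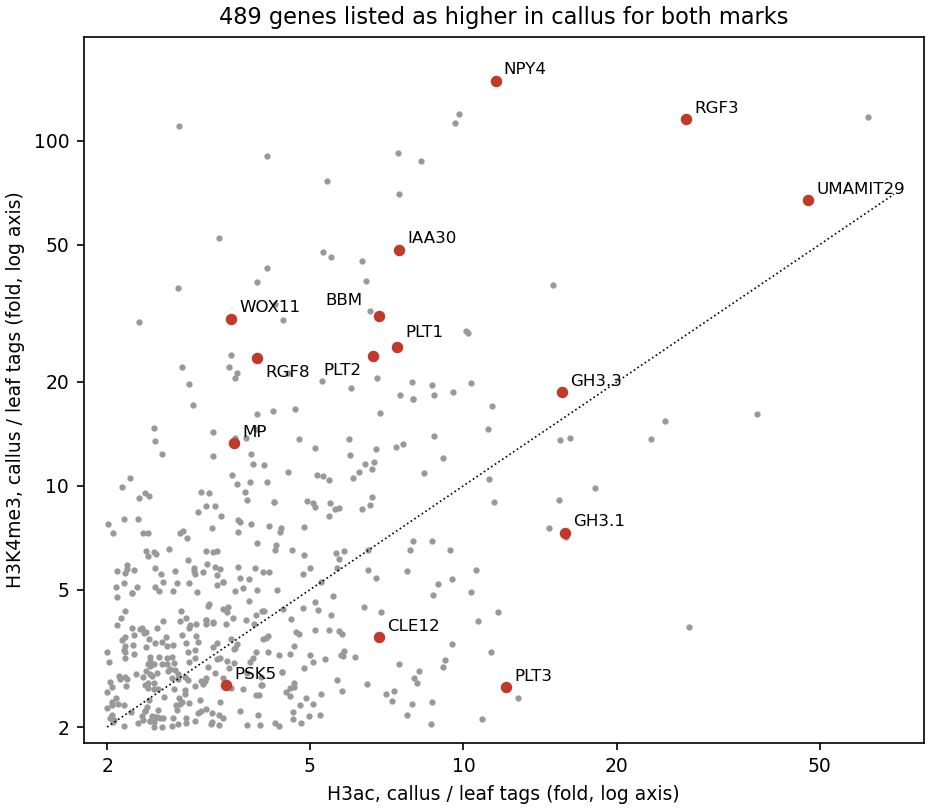
Callus over leaf tag ratios of the 489 genes listed as higher for both marks, H3ac on the horizontal and H3K4me3 on the vertical log axis, 1 point per gene, with equality dotted and genes of the text in red. RGF3 lies at 27.39 and 115.2, and 63.4% of the genes lie above the dotted line.

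H3ac regions higher in callus lay outside genes more often than H3K4me3 ones. Of 1540 nuclear H3ac regions listed as higher, 65.5% touched a gene body with the counted 147 bp, 9.81% lay within 500 bp of a gene and 380 (24.7%) lay farther away. Among H3ac regions called in both tissues and not listed as higher, 4.83% lay farther away, among those called in leaf alone 18%, and among those called in callus alone and not listed 26.1%. Of the 380 listed regions 367 were called in callus alone. For H3K4me3 the share farther away was 4.93% of 1359 listed regions, 2.57% of those called in both tissues and not listed, 5.78% of those called in leaf alone and 8.99% of those called in callus alone and not listed. Listed nuclear H3ac regions had a median length of 369 bp and listed H3K4me3 regions of 647 bp. Calls also differed in number: 2855 nuclear H3ac regions were called in callus alone and 1643 in leaf alone, and for H3K4me3 the numbers were 1355 and 882. Of the callus-alone nuclear regions 47.8% for H3ac and 72.1% for H3K4me3 were listed as higher in the authors' deposited table, and of those called in both tissues 1.1% and 2.35%. The callus H3ac library was also the deeper one, at 1.369 times the depth of leaf.

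**Figure D3:**
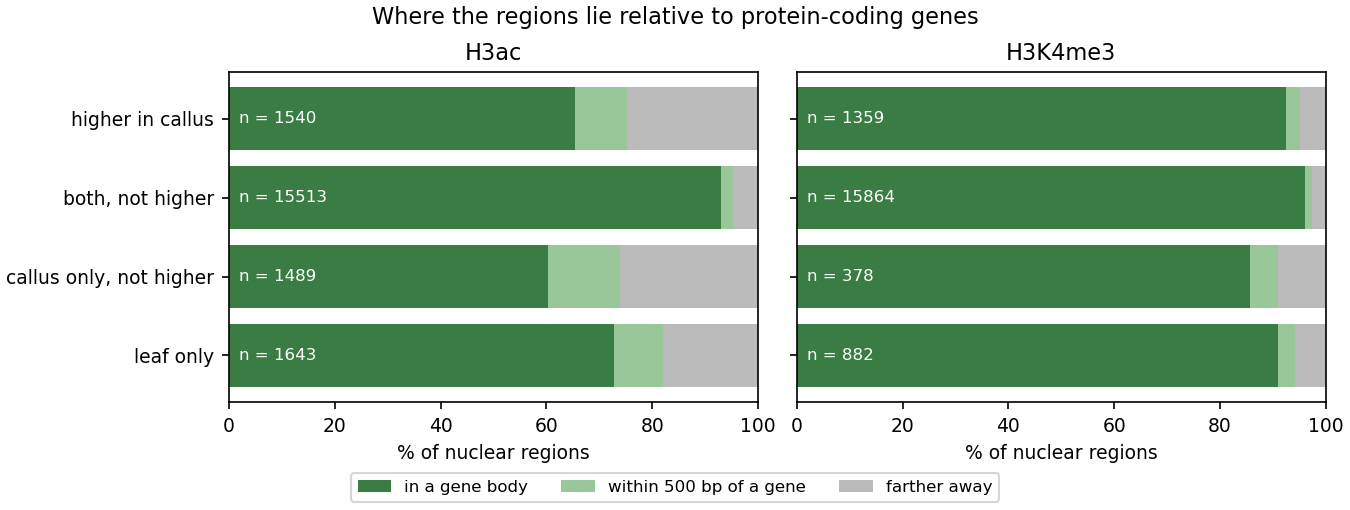
Share of nuclear regions in a gene body, within 500 bp of a gene or farther away, per mark and class of region, with the number of regions in each bar. Regions of H3ac listed as higher lie farther from genes in 24.7% of cases and those of H3K4me3 in 4.93%.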

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

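The tests of library depth and of weak calls in this part were chosen after the results were seen; the others were set before their results were seen. Organelle genomes carry no histones and no gene count above used them, though the totals of merged and listed regions include them. Regions were still called there: 77 for H3ac on the mitochondrial genome, all in callus alone, and 2 for H3ac on the plastid genome in both tissues. These 2 spanned 84.4 and 18.3 kb. The plastid genome also held 81 H3K4me3 regions covering 41.6 kb, 72 of them in leaf alone. Calls of the marks disagreed at a few genes, and this was not tested. A call in leaf alone carries no fold, so it does not show a change in the opposite direction. At 6 genes H3ac was listed as higher in callus while all H3K4me3 regions were called in leaf alone, and at 15 genes the reverse held.

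The 77 mitochondrial H3ac regions had folds of 2.61 to 22.64 in the authors' deposited table, with a median of 5.17. After scaling to the leaf depth, 37 of the 77 passed the exact test on both tag numbers with Bonferroni adjustment. With 0.5 tags as 1 read, 74 passed. At the regions that passed, the tag difference was larger than counting error gives at the depth ratio read from the tag steps. An error in that ratio is not covered. All 77 were listed from the same scaled tags, so the test is no independent check. It does not address which regions were called, so a deeper callus library stays open for the calls. More mitochondrial DNA in the callus immunoprecipitate is a candidate explanation, and it predicted regions in over 50% of bins of 10 kb. They lay in 32.4% (12 of 37 bins), in 4 blocks with a median spacing of 1.13 kb. That prediction was too strict: the plastid H3K4me3 regions also left a stretch from 84.2 to 111 kb empty and ended at 128 kb, where the plastid genome is repeated, so stretches whose reads fit several places may hold no calls. Whether this holds for the empty mitochondrial bins cannot be told apart without the sequence, and no biological explanation was tested.

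The 489 genes higher in callus for both marks could share weak regions rather than a change. Drawing genes at random within cells of both region scores gave a mean of 114 shared genes and at most 145 in 10000 draws, which argues against region score as the whole cause. Extra DNA copies of chromosome segments in callus predicted that over 50% of these genes would have a neighbour listed for both marks, and 13.1% (64 genes) had one, which argues against such copies as the whole cause. Of all genes with regions of both marks 6.13% stood next to a gene listed for both. Neighbouring genes can be given the same region, which may by itself raise the share of such pairs, so clustering is not shown. Smaller copied stretches stay open. A difference between leaf and callus in the marks themselves stays open as a hypothesis, with unequal cell types in the tissues and the single library per tissue and mark untested.

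The 380 H3ac regions higher in callus that lay outside genes could be weak calls, a result of depth or unspecific DNA, and 367 of them were called in callus alone. Weak calls stay open: weighted to the same scores, 14.1% (11.1 to 17.4, central 95% of binomial simulations) of unlisted regions called in both tissues lay outside genes and 28.2% (24 to 32.5) of unlisted regions called in callus alone, against 24.7% of listed ones. After scaling, 58 of the 380 passed the exact test on both tag numbers with Bonferroni adjustment. With 0.5 tags as 1 read, 226 passed. At the regions that passed, the tag difference was larger than counting error gives at the depth ratio read from the tag steps. An error in that ratio is not covered. All 380 were listed from the same scaled tags, so the test is no independent check. It does not address which regions were called, so depth stays open for the calls. More unspecific DNA in the callus H3ac immunoprecipitate stays open too. Plastid DNA, which carries no histones, was called for H3ac over 103 kb in both tissues, so such recovery was not confined to callus. Of the 380, 7.63% overlapped an H3K4me3 region called in callus, which unspecific DNA and acetylated elements away from genes would both give. These cannot be told apart without an input library, and a tissue difference stays untested.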

How the results depend on the processing

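The exact test on both tag numbers, the Bonferroni limits, the unit of 0.5 tags, the count of overlaps by 1 bp, the restriction to nuclear chromosomes, the assignment without flanks and the lists without shared symbols were chosen after the data were seen. With 1 library per group nothing could be left out, and no paired analysis was possible because no group has a second replicate. A limit of 4-fold, which can only lower a count, left 432 H3ac and 541 H3K4me3 regions, 285 and 504 genes, 4 and 8 peptide hormone genes (258 and 78 of 10000 random lists held as many) and 133 genes for both marks. Callus tags at or above the median left 820 and 682 regions, by construction. The exact test on both tag numbers with Bonferroni adjustment left 433 H3ac regions and 1189 H3K4me3 regions, and with 0.5 tags as 1 read it left 1112 and 1350, so the H3ac count rests on what a tag is. In place of shared genes, 510 H3ac regions listed as higher overlapped an H3K4me3 region listed as higher by 1 bp or more and 291 by at least 50% of each other. Random lists matched on gene length reached the H3K4me3 peptide hormone count 0 times in place of 422 and the cause was not tested. Counts within 1.5 times of those reported came from a p limit of 1e-06 (1078 and 1351 regions) and from every other gene assignment (973 to 1158 H3ac genes and 1233 to 1294 H3K4me3 genes). For the other lists, with 26 counts in all, the 4-fold limit moved 17 counts beyond 1.5 times, gene body assignment 1 and leaving out shared symbols 0. Matching on gene length leaves the counts as they are, and the number of random lists holding as many left its binomial 95% interval for 15 of the 26. Rescaling by the median ratio over all regions was not run, since it needs tags of regions not analysed here.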

Other observations

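All tests in this paragraph were chosen after the data were seen. Gene families named by a shared symbol prefix, with at least 10 genes with a region, were counted against random lists matched on region score. Of 99 families for H3ac and 114 for H3K4me3, 2 and 4 had a count of genes higher in callus that fewer than 100 of 10000 random lists reached, where chance gives about 1 each. For genes with regions called in leaf alone the numbers were 0 and 2. WRKY transcription factor genes, known from stress and defence responses, had 11 of 39 listed as higher for H3ac and no random list held as many: WRKY75 at 9.53-fold, WRKY60 at 4.49-fold and WRKY57 at 4.38-fold led in the authors' deposited table. NAC transcription factor genes had 11 of 40 for H3K4me3, which 5 random lists reached, led by NAC084 at 12.03-fold and NAC050 at 4.96-fold in the authors' deposited table. The other families were GSTU for H3ac and GH, IAA and HB for H3K4me3, of which HB mixes homeobox with haemoglobin genes and GH mixes GH3 with GH9 genes, so neither is a family. The 5 GSTU genes stand for 4 regions, as GSTU1 and GSTU2 share 1, and 3 of them lie close together on chromosome 2, so they are not independent. In leaf, SAUR genes were described above, and CRK genes for cysteine-rich receptor-like kinases had 8 of 27 with H3K4me3 regions called in leaf alone, which 2 random lists reached. Most of these, such as CRK5, CRK14 and CRK18, stand in 1 cluster of near copies on chromosome 4, so they are not independent.

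AT3G24240 and AT5G48940, chosen after their values were seen, encode receptor kinases known to bind root meristem growth factor peptides. The authors' deposited table gave them H3K4me3 folds of 87.04 (26.8 to 527) and 39.02 (17.1 to 114), beside the 4 of 9 RGF genes listed as higher for that mark. AT3G24240 was also listed for H3ac with 8.25-fold (3.34 to 26.4) in the authors' deposited table, and AT5G48940 had no H3ac region. The fixed receptor list does not hold either gene. Other receptor genes for these peptides are not described here, so no pattern across such receptors is shown.

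Regions outside genes were also placed by the gene content of their 100 kb bin, chosen after the data were seen. Of the 380 H3ac regions higher in callus outside genes, 5.26% (3.24 to 8.01, exact 95% interval) lay in bins with under 20% gene sequence, against 4.07% (2.12 to 7) of those called in leaf alone and 8.8% (6.87 to 11.1) of those called in both tissues and not listed. Such bins made up 14% of all bins and held 28.3% of the sequence outside genes, and how much of it reads can be placed in is unknown.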
